A study of Caenorhabditis elegans with 16 samples.

How the data were processed

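RNA of whole synchronised Caenorhabditis elegans was measured by a 3′ digital mRNA sequencing service on a NovaSeq instrument (single reads, 100 cycles) in 16 samples. The labels cross 2 genotypes, control and cua-1(H828Q), with plates holding 0 or 100 µM CuCl2, and give 4 samples per group. Worms spent 3 days on the plates at 20 °C. The control strain is not named in the labels, and the allele, a missense change, cannot be read from 3′ counts.

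The deposited table gives raw counts per gene, with no normalization, for 46904 genes and the 16 samples. The authors' processing notes name bcl2fastq, STAR 2.6.0a, HTSeq and the build ce11, without settings, and state neither the annotation release nor the strand setting of the counting. Reads of overlapping genes and of near-identical gene copies (major sperm proteins, nspd peptides, vit-3, vit-4 and vit-5, histones, some collagens) are therefore of uncertain assignment. Each of the 16 columns was matched to its sample by the column heading, and 0 columns were left without a sample. Current symbols came from a RefSeq table, in which 45785 genes were matched by gene identifier. Positions and the length of the longest transcript came from an Ensembl annotation of WBcel235, the same assembly as ce11, and were found for 43064 genes.

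Total counts per library ran from 1891008 to 4001750. Of these counts, 99.45% to 99.78% fell in the genes tested. A floor of 3 counts corresponded to 0.661 to 1.69 CPM (read counts scaled to library size), depending on the library. Where a group held 0 counts of a gene, the fold is given as a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its exact 95% counting interval. These floors and intervals cover counting error only, since reads are not known to be independent molecules.

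Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, filterByExpr with its defaults, 1 mean per group over all 16 libraries (12 residual degrees of freedom), robust dispersion and the quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9787 genes tested. The 5 comparisons were mutant against control without copper, mutant against control with copper, copper against none in the control, copper against none in the mutant, and the interaction of genotype and copper, which is the copper response of the mutant minus that of the control. Fold changes are log2 values with the standard error of the model, CPM values are means with the SD of 4 libraries, and adjusted p refers to edgeR unless a list is named.

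The report names cua-1, the 10 genes with the largest rise and the 10 with the largest fall among called genes with an average log2 CPM of at least 2 and no overlap between the libraries of both groups (no such condition for the interaction), and up to 4 members with the smallest adjusted p of each list discussed. It also names fixed genes of metal and stress responses (mtl-1, mtl-2, hsp-16.2, hsp-4, hsp-6, gst-4, numr-1, chca-1 and cuc-1). This rule and the 33 gene lists were set before the data were examined. Which lists to discuss was chosen after the list results were seen. The lists cover copper, metal and iron handling, stress responses, detoxification, immunity, lipid metabolism, protein and energy metabolism, yolk, germline, cuticle, neurons, muscle, intestine and histones. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. Members called are also counted with p adjusted over the list alone. List medians were also taken with genes of 3 counts or fewer in a group at their bound, which changed 1 of them, named in the report. Changes across genes were compared by correlation and by the overlap of called genes against the number expected for independent calls; genes are not replicates, so a jackknife over libraries gave the standard error.

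Alternatives written down beforehand were DESeq2 size factors and upper-quartile factors, no filter beyond 1 count, a stricter filter (CPM of at least 5 in at least 4 libraries), DESeq2 1.42.0, limma-voom, a fit to the libraries of each comparison alone, the replicate number as a block, a minimum absolute log2 fold change of 1, developmental lists left out, an estimated correlation and fry for lists, and leaving out each of the 16 libraries in turn. After the data were seen, 5 libraries with few counts of long transcripts stood apart. They were defined by the median log2 CPM of genes longer than 3000 bp minus that of genes shorter than 800 bp, below -0.5. For this reason 3 alternatives were added: offsets that remove each library's smooth trend of counts on transcript length (lowess span 0.3), the balance of long and short genes as a covariate, and a fit to the same genes without the 5 libraries. The last leaves the untreated control with 1 library, which is assumed to vary like the other groups. A lone library decides every value of that fit that involves the untreated control.

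The pipeline was tested on simulated data with 100 genes changed at each fold, drawn from genes with an average log2 CPM above 2. At fold 2 it recovered 17%, 8%, 9%, 16% and 2% in the 5 comparisons, in the order above. At fold 4 the shares were 75%, 78%, 69%, 77% and 31% in that order. Unchanged genes called numbered 0, 5, 4, 3 and 2, out of 9410 to 9507 genes simulated. In a simulation with only a length trend between libraries, 0 of 9516 genes were called in any comparison, with or without the length offsets (edgeR). The unadjusted p was under 0.05 for 1079 of these genes in mutant against control without copper, and for 482 with the offsets. Calls from real depletion are not excluded: the 4 control libraries with few long transcripts against the other 4 gave 4028 genes. In a test of the lists, the 1 list raised on purpose was called and 0 others. Genes were drawn independently of each other there, so it does not measure false calls in lists whose members move together.

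For each count of genes or lists, other splits of the same libraries into equal groups were run, all 35 where 2 groups are compared and 100 drawn ones for the interaction and for the correlation of the copper responses. No sample or gene with a count was left out of the deposited table before filtering, and 12 protein genes of the mitochondrial genome held 0 counts in all 16 libraries.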

Results

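RNA of whole worms was counted in 16 libraries, 4 for each combination of genotype (control or cua-1(H828Q)) and plate (no added copper or 100 µM CuCl2). The gene cua-1 encodes the copper-transporting ATPase of the worm, the homolog of the human copper pumps of Menkes and Wilson disease. The tests covered 9787 genes. Values after ± are the SD of 4 libraries for normalised read counts (CPM) and the model's standard error for log2 fold changes.

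A balance of long against short transcripts separated 5 libraries from the rest. In these 5, genes longer than 3000 bp were scarce against genes shorter than 800 bp, with differences in median log2 CPM of -2.16, -0.99 and -0.68 in untreated control replicates 1, 3 and 4, -0.87 in copper-treated control replicate 1 and -2.28 in copper-treated mutant replicate 4. The remaining libraries ran from 0.19 to 1.09. The 5 are called long-depleted here, a group drawn from the data and not from the labels. The first principal component, with 47.5% of the variance, held them at -101 to -38 and the remaining libraries at 10.5 to 49. Ribosomal protein genes took 35.5% to 38.7% of their counts, against 25.4% to 31.8% in the remaining libraries.

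**Figure D1:**
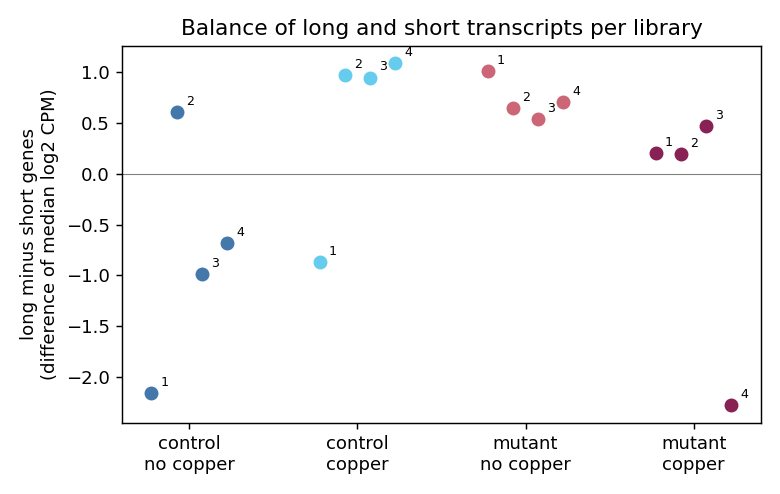
Each point is 1 library, numbered by replicate, with the 4 groups on the horizontal axis and, on the vertical axis, the median log2 CPM of genes longer than 3000 bp minus that of genes shorter than 800 bp. The long-depleted libraries lie at -2.28 to -0.68 and number 3 in the untreated control, 1 in each copper-treated group and 0 in the untreated mutant.

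The copper ATPase gene itself, cua-1 (WBGene00000834, WBcel235 chromosome III, 13439730 to 13455307, minus strand), was counted at 11.8 ± 7.33 CPM in the untreated control, 24.6 ± 9.29 in the copper-treated control, 29.3 ± 7.21 in the untreated mutant and 17.7 ± 7.15 in the copper-treated mutant. It was called only in the untreated mutant against the untreated control, at 1.29 ± 0.43 (adjusted p = 0.0429), and this call ended in 16 of 29 alternatives, with adjusted p from 0.00871 to 0.44. Without the long-depleted libraries the value was 0.36 (adjusted p = 0.44). Its fold change was -0.47 ± 0.42 for the mutant on copper (adjusted p = 0.654), 1.03 ± 0.43 for copper in the control (adjusted p = 0.225) and -0.72 ± 0.41 for copper in the mutant (adjusted p = 0.509), with an interaction of -1.75 ± 0.60 (adjusted p = 0.0942).

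Mutant against control without copper asks how the mutant differs on plates with no added metal. The labels do not name the control strain, so reading a difference between genotypes as an effect of the mutation assumes a shared background. The untreated mutant held little of the long non-coding RNA tts-1, known from long-lived and dauer worms: 4.06 ± 2.6 CPM against 669 ± 575 in the control. The acyl-CoA synthetase gene acs-2, which acts in fat breakdown, went from 26 ± 15.4 to 1.89 ± 0.558 CPM, and the genes of the gut cysteine proteases cpr-1 and cpr-4 fell by 2.71 ± 0.37 and 2.46 ± 0.35 on the log2 scale. The metallothionein gene mtl-2, which binds metals, fell from 88.9 ± 66.1 to 15.9 ± 3.74 CPM, where untreated control replicate 2 held 43. Small peptide genes of sperm rose, and so did long genes such as che-10 and him-4. Of the long-depleted libraries, 3 are in the untreated control and 0 in the untreated mutant.

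The fold change of tts-1 was -7.34 ± 0.74 (adjusted p = 0.000152), that of acs-2 -3.75 ± 0.51 (adjusted p = 0.000663) and that of mtl-2 -2.48 ± 0.50 (adjusted p = 0.00601). These values were -6.07, -3.43 and -1.48 without the long-depleted libraries. Other large falls were dod-3 (-4.66 ± 0.82), a gene regulated by the DAF-16 transcription factor, scl-2 (-3.88 ± 0.53), a secreted protein gene, T12D8.5 (-3.87 ± 0.54), F45D3.4 (-3.74 ± 0.55) and C06B3.6 (-3.54 ± 0.55), with adjusted p between 0.000663 and 0.0027. The largest rises included che-10 (4.92 ± 0.97), a ciliary rootlet gene, cls-3 (4.44 ± 0.85), of the microtubule-binding CLASP family, him-4 (4.40 ± 0.83), the matrix protein hemicentin, AC3.5 (4.32 ± 0.60) and T22B7.7 (4.17 ± 0.71), with adjusted p from 0.000695 to 0.00519. With 3 counts in the untreated control, C42D4.2 gave a ratio of 23.6 (95% interval 7.88 to 116) and C41A3.2 a ratio of 20.5 (6.85 to 101). T04F3.1 (5.09 ± 0.95) and F21C10.7 (4.27 ± 0.83) lost their calls without the long-depleted libraries (adjusted p = 0.0879 and 0.163). Genes called higher had a median transcript length of 1584 bp and genes called lower 887 bp, against 1381.5 bp over all genes tested. With the length offsets the order turned, to 1167 and 1319 bp.

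Of 41 immune effector genes, 20 fell and 0 rose (25 and 0 adjusted over the list alone; median -1.05, adjusted p = 3.19e-08, and adjusted p = 0.548 with an estimated correlation). Examples were the caenacin cnc-4 (-3.23 ± 0.44), the saposin-like spp-18 (-2.59 ± 0.44) and the lysozymes lys-4 (-1.74 ± 0.32) and lys-5 (-2.68 ± 0.50). Without the long-depleted libraries 11 fell and 2 rose, with a median of -0.35. Sperm genes moved the other way, with 12 of 50 higher and 0 lower (12 and 0 adjusted over the list alone; median 0.72, adjusted p = 2.42e-06, and adjusted p = 0.686 with an estimated correlation). Here nspd-6 rose by 1.51 ± 0.29, nspd-10 by 1.39 ± 0.29 and nspd-4 by 1.07 ± 0.26, and without the long-depleted libraries 46 rose (median 1.85). The 1 untreated control library of that fit, replicate 2, lay apart in this list, with a score (mean log2 CPM of the members, each centred over the 16 libraries) of -1.2 against 0.035 to 0.15 in the rest of its group. Of 31 oocyte and embryo genes, 15 fell and 0 rose (20 lower and 1 higher adjusted over the list alone; median -0.63, adjusted p = 6e-06, and adjusted p = 0.548 with an estimated correlation). The number that fell was 15 without the long-depleted libraries too. The eggshell genes perm-2 (-1.31 ± 0.33) and cpg-2 (-1.02 ± 0.26) each lost the call without 1 library, perm-2 without untreated control replicate 1 (adjusted p = 0.0532) and cpg-2 without untreated mutant replicate 4 (adjusted p = 0.0564).

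Ribosomal protein genes fell in 51 of 80 cases with 0 rising (77 and 0 adjusted over the list alone; median -0.93, adjusted p = 2.23e-15, and adjusted p = 0.612 with an estimated correlation). Without the long-depleted libraries 0 fell and 1 rose, with a median of 0.013, while 20 fell with the length offsets (median -0.38); rps-4 went from -1.05 ± 0.30 to -0.10 (adjusted p = 0.637) and rpl-35 from -1.07 ± 0.31 to 0.0025 (adjusted p = 0.994). Of 35 histone genes 23 fell and 1 rose (26 and 2 adjusted over the list alone; median -1.25, adjusted p = 5.46e-08, and adjusted p = 0.548 with an estimated correlation). Examples were hil-3 (-2.33 ± 0.47) and his-61 (-1.79 ± 0.37), and without the long-depleted libraries 10 fell and 2 rose. Histones were counted from messages that mostly lack a poly(A) tail, and their copies are near-identical. Of 61 autophagy and lysosome genes 17 fell and 3 rose (18 and 3 adjusted over the list alone; median -0.17, adjusted p = 0.0147, and adjusted p = 0.548 with an estimated correlation). That list was not called without the long-depleted libraries (adjusted p = 0.0877). It included the aspartyl protease asp-12 (-1.99 ± 0.26), the autophagy receptor sqst-1 (-1.77 ± 0.26) and lgg-2 (-1.28 ± 0.23). Detoxification enzymes rose in 12 of 69 cases and fell in 7 (17 and 7 adjusted over the list alone; median 0.51, or 0.49 with 2 genes at their bound, adjusted p = 0.0256, and adjusted p = 0.548 with an estimated correlation). Here ugt-12 rose by 1.74 ± 0.28 and cyp-34A9 fell by 2.28 ± 0.52.

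Copper handling genes were not called as a list (adjusted p = 0.186): 2 of 16 rose and 6 fell, the same numbers adjusted over the list alone, and 2 rose and 0 fell without the long-depleted libraries. The copper chaperone cuc-1 fell by 1.06 ± 0.34 (adjusted p = 0.0376), a call lost in 10 of 29 alternatives, with adjusted p from 0.0114 to 0.406. The list of metal-responsive genes was not called either (adjusted p = 0.524; 3 of 11 lower, and 4 lower and 1 higher adjusted over the list alone). Its ttm-1, a zinc transporter gene, went from -1.14 ± 0.37 to 0.46 without the long-depleted libraries. F58G6.9 (chca-1), hsp-4, hsp-6 and gst-4 were not called (adjusted p = 0.825, 0.6, 0.466 and 0.169). The inducible genes mtl-1, hsp-16.2, hsp-70 and sod-3 were too low to test, with 15, 51, 22 and 80 counts over the 16 libraries, and numr-1 and numr-2 had 0.

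In all, 2141 genes were called, 919 higher and 1222 lower (edgeR). Without the long-depleted libraries, and so with 1 untreated control library, the count was 1716 (1089 higher and 627 lower), of which 950 were also called, in the same direction, with all libraries. The count was 880 with the covariate (649 higher and 231 lower, 647 shared) and 1419 with the replicate block. It was 839, 3838 and 892 without untreated control replicates 1, 2 and 3, 749, 778, 917 and 735 without untreated mutant replicates 1 to 4, and 3299 without copper-treated mutant replicate 4.

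Mutant against control on copper asks how the mutant differs once both genotypes meet the metal. The copper-treated mutant had fewer transcripts of the yolk gene vit-5, 473 ± 224 CPM against 2970 ± 267 in the control, and more of the cuticle collagen dpy-13, 92.6 ± 28.1 CPM against 2.03 ± 2.15. Sperm genes and neuropeptide genes rose as groups (adjusted p = 1.96e-25 and 2.19e-16, but 0.185 for each with an estimated correlation). Defence genes split: the infection response gene irg-5 stood at 98 ± 21.7 CPM against 8.42 ± 2.21, while the lysozyme lys-7 stood at 27 ± 8.38 against 220 ± 24.8. Of the long-depleted libraries, 1 is in each of these groups.

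All 6 vitellogenin genes fell (6 also adjusted over the list alone; median -2.33, adjusted p = 2.01e-18, and adjusted p = 0.0598 with an estimated correlation). The values were -2.93 ± 0.39 for vit-4, -2.65 ± 0.37 for vit-5 (WBcel235 chromosome X, 3403471 to 3408603), -2.34 ± 0.35 for vit-3 and -2.32 ± 0.29 for vit-1. The fall covered all 6 genes without the long-depleted libraries as well. Cuticle collagen genes moved the other way, with 62 of 99 higher and 0 lower (74 and 1 adjusted over the list alone; median 2.83, adjusted p = 3.75e-46, and adjusted p = 0.183 with an estimated correlation). Among them dpy-13 rose by 5.63 ± 0.85 (adjusted p = 0.000757), col-73 by 5.63 ± 0.88, col-157 by 5.07 ± 0.59, col-161 by 4.25 ± 0.57, col-39 by 3.99 ± 0.56 and col-12 by 3.58 ± 0.46. The collagen col-17, with 3 counts in the control, gave a ratio of 58.8 (19.8 to 287). In the fit without the long-depleted libraries 87 collagens rose and 2 fell. Of 19 molting genes 3 rose and 0 fell, the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.215), though it was with the length offsets (0.0263) and with fry (0.0278). They were mlt-8 (2.85 ± 0.65, lost without copper-treated control replicate 4 at adjusted p = 0.0519), mlt-9 (ratio 14.1, 4.56 to 70.5) and qua-1 (3.55 ± 1.01, lost in 14 of 27 alternatives, adjusted p from 0.000225 to 0.142).

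Sperm genes rose in 35 of 50 cases and fell in 0 (48 and 0 adjusted over the list alone; median 1.46, adjusted p = 1.96e-25, and adjusted p = 0.185 with an estimated correlation). The major sperm protein gene msp-76 rose by 1.61 ± 0.30 and the small sperm peptide genes nspd-6 and nspd-2 by 1.55 ± 0.29 and 1.49 ± 0.30. The related nspd-4 (1.61 ± 0.27) lost its call with the length offsets (adjusted p = 0.0682). Of 39 neuropeptide genes 17 rose and 0 fell (28 and 0 adjusted over the list alone; median 1.34, adjusted p = 2.19e-16, and adjusted p = 0.185 with an estimated correlation). The insulin-like ins-37 was at 2.81 ± 0.39 and the FMRFamide-like peptides flp-8 at 2.28 ± 0.45, flp-1 at 1.88 ± 0.32 and flp-14 at 1.78 ± 0.39. Counts without the long-depleted libraries were 43 sperm and 29 neuropeptide genes higher, with 0 lower in each list. Muscle genes as a list were called higher (2 of 26 higher and 0 lower, the same adjusted over the list alone; median 0.60, adjusted p = 0.00116, and adjusted p = 0.185 with an estimated correlation). Both members were troponin genes with calls that depended on the alternative: tnc-2 (1.66 ± 0.45) lost it in 9 of 29, with adjusted p from 0.0113 to 0.137, and tni-1 (0.89 ± 0.26) in 18 of 29, with adjusted p from 3.03e-06 to 0.173.

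Immune effector genes rose in 10 of 41 cases and fell in 3 (10 and 5 adjusted over the list alone; median 0.66, adjusted p = 0.00107, and adjusted p = 0.74 with an estimated correlation). The list's call was also lost with the length offsets (adjusted p = 0.321). The infection response gene irg-5 (chromosome V, 13737010 to 13738474) rose by 3.54 ± 0.34 (adjusted p = 2.7e-05), dod-24 by 2.31 ± 0.34 and the caenacin cnc-10 by 1.93 ± 0.25. The lysozyme lys-7 (chromosome V, 3481432 to 3482600) fell by 3.03 ± 0.30 (adjusted p = 2.99e-05) and T24B8.5 (chromosome II, 9082626 to 9083193), a gene of the p38 MAPK immune pathway, by 2.42 ± 0.38. C-type lectin genes rose in 16 of 58 cases and fell in 2 (20 and 4 adjusted over the list alone; median 0.51, adjusted p = 1.54e-05, and adjusted p = 0.185 with an estimated correlation). The clearest rises were clec-52 (4.18 ± 0.37), clec-67 (2.88 ± 0.48), clec-47 (2.86 ± 0.37) and clec-66 (2.17 ± 0.36). Among 69 detoxification enzymes 8 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.41, adjusted p = 0.0104, and adjusted p = 0.185 with an estimated correlation and 0.0707 without the long-depleted libraries). The glutathione S-transferases gst-38, gst-24 and gst-6 rose by 4.64 ± 0.66, 3.66 ± 0.50 and 2.31 ± 0.35. The UDP-glucuronosyltransferase ugt-13 rose by 2.3 ± 0.38 and the cytochrome P450 cyp-35A2 fell by 2.45 ± 0.42.

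The fat breakdown gene acs-2 rose by 3.41 ± 0.51 (adjusted p = 0.000654). In its list 3 of 31 lipid breakdown genes rose with 0 lower, the same adjusted over the list alone, and the list was not called (adjusted p = 0.776). The stearoyl-CoA desaturase fat-7 fell by 1.47 ± 0.30 (adjusted p = 0.0061), the 1 call among 18 fatty acid synthesis genes, also 1 adjusted over the list alone (list adjusted p = 0.0593). The aspartyl protease genes asp-12, asp-14 and asp-8 rose by 3.12 ± 0.27, 2.90 ± 0.37 and 2.6 ± 0.49, the 3 calls among 61 autophagy and lysosome genes, again 3 adjusted over the list alone (list adjusted p = 0.791). The S-adenosylmethionine synthetase sams-5 (1.73 ± 0.41) lost its call without copper-treated control replicate 3 (adjusted p = 0.0603), and it was 1 of 2 calls in the methionine list, both also adjusted over the list alone (list adjusted p = 0.776). Metal-responsive genes were not called as a list (adjusted p = 0.458; 2 of 11 higher, also 2 adjusted over the list alone). Their cadmium-responsive cdr-2 (1.26 ± 0.35) and cdr-4 (1.15 ± 0.32) lost their calls in 10 and 12 of 29 alternatives, with adjusted p up to 0.14 and 0.123. Copper handling genes were called neither singly (edgeR, 0 of 16, also 0 adjusted over the list alone) nor as a list (adjusted p = 0.776). The metallothionein mtl-2 was at -0.12 ± 0.48 (adjusted p = 0.918) and cuc-1 at -0.25 ± 0.34 (adjusted p = 0.754). F58G6.9, hsp-4 and hsp-6 were not called (adjusted p = 0.973, 0.767 and 0.946), and gst-4, a reporter gene of oxidative stress, was at 1.82 ± 0.48 (adjusted p = 0.0253, lost in 7 of 29 alternatives, 0.0047 to 0.0951).

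The other genes with the largest rises were E01G4.6, at least 74.2-fold higher, B0348.2 (5.96 ± 0.83) and the hedgehog-like grl-16 (5.5 ± 1). With 1 or 2 counts in the control, others were F44G3.10 (ratio 70.7, 19.3 to 588), C25F9.11 (69.1, 18.8 to 575), F35B3.4 (68.7, 18.7 to 572) and K02E11.10 (91, 16 to 3630). The last lost its call without copper-treated control replicate 4 (adjusted p = 0.0529). Among the largest falls were oac-20 (-3.25 ± 0.38, adjusted p = 0.000128), an O-acyltransferase-like gene, C50F7.5 (-3.02 ± 0.54), C55C3.3 (-2.62 ± 0.28) and ZK673.1 (-2.49 ± 0.41). E02H4.7 (-2.63 ± 0.65) lost its call with limma-voom and without copper-treated mutant replicates 2 or 3 (adjusted p from 0.000702 to 0.077 over all alternatives). In all, 678 genes were called, 625 higher and 53 lower (edgeR), with median lengths of 871 and 1233 bp (1024 and 682 bp with the length offsets). The count was 434 and 449 without copper-treated control replicates 3 and 4, 1530 with the covariate and 2288 without the long-depleted libraries (1454 higher and 834 lower, with 676 of the calls shared).

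Copper against none in the control asks how the control worms respond to 100 µM CuCl2. The immune reporter gene T24B8.5 went from 6 ± 3.28 to 156 ± 43.7 CPM, the C-type lectin gene clec-41 from 35.8 ± 15.2 to 191 ± 32.6 and lys-7 from 45.4 ± 19.3 to 220 ± 24.8. In the other direction, the alcohol dehydrogenase gene sodh-1 went from 35.6 ± 20.7 to 1.42 ± 0.835 CPM and acs-2 from 26 ± 15.4 to 2.76 ± 2.06. Cuticle collagen genes fell as a group (adjusted p = 1.42e-17, but 0.621 with an estimated correlation), with untreated control replicate 1 far above its group and a median of -0.37 in place of -1.65 without the long-depleted libraries. Of the long-depleted libraries, 3 are in the untreated and 1 in the copper-treated group.

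The rise was 4.71 ± 0.43 for T24B8.5 (adjusted p = 1.76e-05), 3.30 ± 0.27 for F55G11.4, a gene of a CUB-like family (adjusted p = 7.38e-06), and 3.24 ± 0.41 for oac-20 (adjusted p = 0.000441). It was 3.07 ± 0.44 for F01D5.5, 2.42 ± 0.29 for clec-41 (adjusted p = 0.000258) and 2.28 ± 0.29 for lys-7 (adjusted p = 0.000471). The lectin clec-45 (chromosome V, 7638101 to 7638657) rose by 4.12 ± 0.69 (adjusted p = 0.00551), a call lost in the fit to these libraries alone (adjusted p = 0.131). The call of cls-3 (4.53 ± 0.86) was lost with limma-voom and without untreated control replicate 1 (adjusted p from 4.25e-05 to 0.127). The lectin clec-43 was at least 9.24-fold higher, a call lost in 6 of 27 alternatives (0.000878 to 0.0796). AC3.5 (2.99 ± 0.59), F01D5.1 (2.70 ± 0.66), C41A3.2 and C42D4.2 (each with a ratio of 15.1, 4.94 to 75.6) lost their calls in 6 of 29, 15 of 29, 15 of 28 and 12 of 28 alternatives, with adjusted p up to 0.187, 0.177, 0.167 and 0.151. C-type lectin genes rose in 3 of 58 cases and fell in 4 (4 and 9 adjusted over the list alone), among them clec-52 at -2.40 ± 0.37, whose call was lost in the fit to these libraries alone and without the long-depleted libraries (adjusted p = 0.121 and 0.0908). That list was not called (adjusted p = 0.337).

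The falls of sodh-1 (-4.64 ± 0.55, adjusted p = 0.000244), the aspartyl protease asp-12 (-2.76 ± 0.27, adjusted p = 2.4e-05) and the collagen sqt-3 (-4.20 ± 0.54, adjusted p = 0.000471) were called in every alternative that tested them. Of 99 collagen genes 22 fell and 0 rose (49 and 0 adjusted over the list alone; median -1.65, adjusted p = 1.42e-17, and adjusted p = 0.621 with an estimated correlation). In the fit without the long-depleted libraries 25 collagens fell and 10 rose (median -0.37). Further collagens among the largest falls were col-73 (-4.90 ± 0.87), rol-8 (-4.74 ± 0.97), col-14 (-4.64 ± 0.84), dpy-13 (-4.38 ± 0.83), col-60 (-3.75 ± 0.74) and col-17 (46.3-fold lower, 15.4 to 228). Each of these lost its call in 4 to 8 alternatives, with highest adjusted p of 0.196, 0.141, 0.129, 0.22, 0.22 and 0.207. E01G4.6 was at least 21.6-fold lower and F35B3.4 19.5-fold lower (4.94 to 168), calls lost in 16 and 14 of 28 alternatives (adjusted p up to 0.215 and 0.225). Untreated control replicate 1 lay apart in this list, with a score of 1.5 against -0.66 to -0.41 in the rest of its group.

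Immune effector genes rose in 4 of 41 cases and fell in 11 (6 and 24 adjusted over the list alone; median -1.02, adjusted p = 0.000129, and adjusted p = 0.621 with an estimated correlation). The list was no longer called with the length offsets (adjusted p = 0.104) or without the long-depleted libraries (adjusted p = 0.0905; 7 rose and 10 fell). In the fit to these libraries alone cnc-4 (-2.84 ± 0.44) and lys-4 (-1.90 ± 0.33) lost their calls (adjusted p = 0.0815 and 0.121). The fat breakdown gene acs-2 fell by 3.23 ± 0.51 (adjusted p = 0.00344; 0.125 in the fit to these libraries alone), the 1 call among 31 lipid breakdown genes (6 lower adjusted over the list alone; list adjusted p = 0.0979, but 0.01 with the length offsets). Autophagy and lysosome genes fell in 2 of 61 cases with 0 higher (11 and 0 adjusted over the list alone; median -0.13, adjusted p = 0.0196, and adjusted p = 0.621 with an estimated correlation). They were asp-8 at -2.3 ± 0.50 and asp-12. The gut proteases cpr-1 (-1.82 ± 0.35) and cpr-4 (-1.56 ± 0.34) were the 2 calls among 20 intestine genes (7 lower and 1 higher adjusted over the list alone; list adjusted p = 0.0813, but 0.00683 with the length offsets). The calls of asp-8, cpr-1 and cpr-4 ended in 7, 7 and 9 of 29 alternatives, with adjusted p up to 0.29, 0.196 and 0.261. Detoxification enzymes were not called as a list (adjusted p = 0.861; 1 of 69 higher and 2 lower, the same adjusted over the list alone), with the cytochrome P450 cyp-34A9 at -3.14 ± 0.58 (lost without copper-treated control replicate 4, adjusted p = 0.061).

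Copper handling genes were called neither singly nor as a list (edgeR, 0 of 16, and 1 higher adjusted over the list alone; list adjusted p = 0.0979). Among them were Y58A7A.1, a copper transporter of the CTR family, at 1.65 ± 0.47 (adjusted p = 0.0841), K12C11.6 at -1.97 ± 0.65 (adjusted p = 0.141), F58G6.9 at -1.06 ± 0.40 (adjusted p = 0.2) and the chaperone cuc-1 at -0.87 ± 0.34 (adjusted p = 0.205). Metal-responsive genes were not called either (0 of 11, and 4 lower adjusted over the list alone; list adjusted p = 0.333), and mtl-2 was at -1.53 ± 0.49 (adjusted p = 0.127). The stress genes hsp-4, hsp-6 and gst-4 were not called (adjusted p = 0.548, 0.928 and 0.633). In the control 174 genes were called, 45 higher and 129 lower (edgeR), with median lengths of 1519 and 924 bp (1013 and 1031 bp with the length offsets). The count was 60, 849 and 429 without untreated control replicates 1, 2 and 4, 306, 73, 53 and 44 without copper-treated control replicates 1 to 4. It was 440 with DESeq2, 45 with limma-voom, 13 in the fit to these libraries alone, 64 with the replicate block and 1.0e+02 with the covariate (46 higher and 58 lower). It was 468 without the long-depleted libraries (232 higher and 236 lower, 122 shared).

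Copper against none in the mutant asks the same of worms with the altered pump. The infection response gene irg-5 went from 1.09 ± 0.757 to 98 ± 21.7 CPM, the lysozyme lys-2 from 89.5 ± 35.2 to 611 ± 117 and tts-1 from 4.06 ± 2.6 to 100 ± 10.7. The yolk gene vit-5 went from 2290 ± 139 to 473 ± 224 CPM. Immune, lectin, collagen and neuropeptide genes rose as groups and vitellogenins fell. With an estimated correlation none of these 5 lists was called (adjusted p = 0.424, 0.145, 0.455, 0.455 and 0.0871). Of the long-depleted libraries, 1 is in the treated and 0 in the untreated group.

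The fold change of irg-5 was 6.45 ± 0.41 (adjusted p = 1.19e-07), that of tts-1 (chromosome X, 1504131 to 1504841) 4.60 ± 0.66 (adjusted p = 0.000643) and that of acs-2 (chromosome V, 15567394 to 15569897) 3.94 ± 0.51 (adjusted p = 0.00032). With 3 counts each in the untreated mutant, clec-45 gave a ratio of 180 (61.4 to 878) and F19H6.5 of 120 (40.6 to 583). The same held for the mucin-like mul-1, at 84.1 (28.4 to 411), and gst-35, at 51.3 (17.2 to 252). Other large rises were B0348.2 (5.30 ± 0.75), clec-3 (4.95 ± 0.68), the pseudogene Y54H5A.5 (4.45 ± 0.50), col-65 (4.41 ± 0.72) and F44G3.10 (4.16 ± 0.63). Large falls were T22B7.7 (-3.84 ± 0.64, adjusted p = 0.00264), E02H4.7 (-3.77 ± 0.60), drd-10 (-3.34 ± 0.39, adjusted p = 0.000123), and D1086.3 (-3.22 ± 0.61). Others were the lectin clec-218 (-3.12 ± 0.48), cyp-35A2 (-2.73 ± 0.42) and the glucocerebrosidase-like gba-4 (-2.71 ± 0.42). The laminin gene lam-3 (-3.26 ± 0.76), asp-17 (-3.14 ± 0.67) and C33G8.2 (-2.73 ± 0.65) lost their calls in 7, 4 and 9 of 29 alternatives, with adjusted p up to 0.128, 0.0755 and 0.138.

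Immune effector genes rose in 10 of 41 cases and 1 fell (16 and 2 adjusted over the list alone; median 0.74, adjusted p = 1.9e-14, and adjusted p = 0.424 with an estimated correlation). Besides irg-5, irg-4 rose by 3.58 ± 0.46, dod-24 by 3.53 ± 0.36 (adjusted p = 3.77e-05) and lys-2 by 2.77 ± 0.34, and 18 rose and 3 fell without the long-depleted libraries. C-type lectins rose in 13 of 58 cases and fell in 2 (17 and 2 adjusted over the list alone; median 0.51, adjusted p = 1.9e-09, and adjusted p = 0.145 with an estimated correlation). Among them were clec-52 (3.15 ± 0.33) and clec-66 (2.63 ± 0.36). The vitellogenin list had 4 of 6 genes lower and 0 higher (6 and 0 adjusted over the list alone; median -2.14, adjusted p = 1.64e-16, and adjusted p = 0.0871 with an estimated correlation). The values were -2.66 ± 0.38 for vit-4, -2.48 ± 0.29 for vit-1, -2.27 ± 0.37 for vit-5 and -2.01 ± 0.35 for vit-3. All 6 fell without the long-depleted libraries. Collagens rose in 18 of 99 cases with 0 lower (43 and 2 adjusted over the list alone; median 1.16, adjusted p = 9.91e-18, and adjusted p = 0.455 with an estimated correlation). Examples were col-91 at 3.71 ± 0.61, col-162 at 3.62 ± 0.63 and col-161 at 2.88 ± 0.50. Neuropeptide genes rose in 3 of 39 cases with 0 lower (14 and 0 adjusted over the list alone; median 0.84, adjusted p = 2.21e-09, and adjusted p = 0.455 with an estimated correlation). They were flp-34 (2.72 ± 0.54), flp-8 (1.89 ± 0.42) and flp-24 (1.61 ± 0.41), the last 2 with calls lost in 5 and 10 of 29 alternatives (adjusted p up to 0.0968 and 0.163).

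Fatty acid synthesis genes fell in 2 of 18 cases with 0 higher (7 and 0 adjusted over the list alone; median -0.43, adjusted p = 0.000406, and adjusted p = 0.424 with an estimated correlation). The desaturase fat-7 fell by 1.65 ± 0.30 (adjusted p = 0.00567), and acs-1 (-1.5 ± 0.37) lost its call in 12 of 29 alternatives (adjusted p up to 0.0993). Detoxification enzymes rose in 4 of 69 cases and fell in 3 (7 and 8 adjusted over the list alone; list adjusted p = 0.889), with gst-38 at 3.54 ± 0.57 and gst-24 at 2.6 ± 0.44. Lipid breakdown genes rose in 2 of 31 cases, the same adjusted over the list alone (list adjusted p = 0.93): beside acs-2, ech-9 stood at 2.58 ± 0.61 (lost in 8 of 29 alternatives, adjusted p up to 0.138). Among 61 autophagy and lysosome genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.676), with asp-14 at 2.72 ± 0.37, asp-12 (chromosome V, 8269210 to 8272056) at 2.35 ± 0.26 and sqst-1 at 1.51 ± 0.25. Copper handling and metal-responsive genes were not called singly or as lists (edgeR, 0 of 16 and 0 of 11, also 0 adjusted over the list alone; list adjusted p = 0.889 and 0.667). The fixed genes mtl-2 (0.82 ± 0.49), cuc-1, F58G6.9, hsp-4, hsp-6 and gst-4 had adjusted p of 0.522, 0.94, 0.357, 0.843, 0.678 and 0.61.

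For copper in the mutant 219 genes were called, 174 higher and 45 lower (edgeR), with median lengths of 974 and 1276 bp (986 and 1166 bp with the length offsets). The count was 334 without untreated control replicate 1, 115, 121 and 126 without untreated mutant replicates 1, 2 and 4, and 121 without copper-treated mutant replicate 2. It was 432 with DESeq2, 472 in the fit to these libraries alone, 403 with the covariate and 1420 without the long-depleted libraries (746 higher and 674 lower, 219 shared).

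The interaction asks whether the copper response of the mutant differed from that of the control. It did for 527 genes, 402 with a more positive and 125 with a more negative response in the mutant (edgeR). The gene acs-2 was lower with copper in the control and higher in the mutant, with an interaction of 7.16 ± 0.72 (adjusted p = 4.58e-05). The protease gene asp-12 followed the same course, from 125 ± 47.4 to 18.4 ± 1.39 CPM in the control and from 31.3 ± 5.63 to 160 ± 15.4 in the mutant (5.11 ± 0.38, adjusted p = 1.16e-06). The non-coding tts-1 went from 669 ± 575 to 66.2 ± 17.3 CPM in the control (-3.34 ± 0.60, adjusted p = 0.00871) and from 4.06 ± 2.6 to 100 ± 10.7 in the mutant (interaction 7.93 ± 0.90, adjusted p = 0.000133). The lysozyme lys-7 rose in the control and stood at 30.5 ± 3.75 and 27 ± 8.38 CPM in the mutant (-2.46 ± 0.41, adjusted p = 0.00211).

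**Figure D2:**
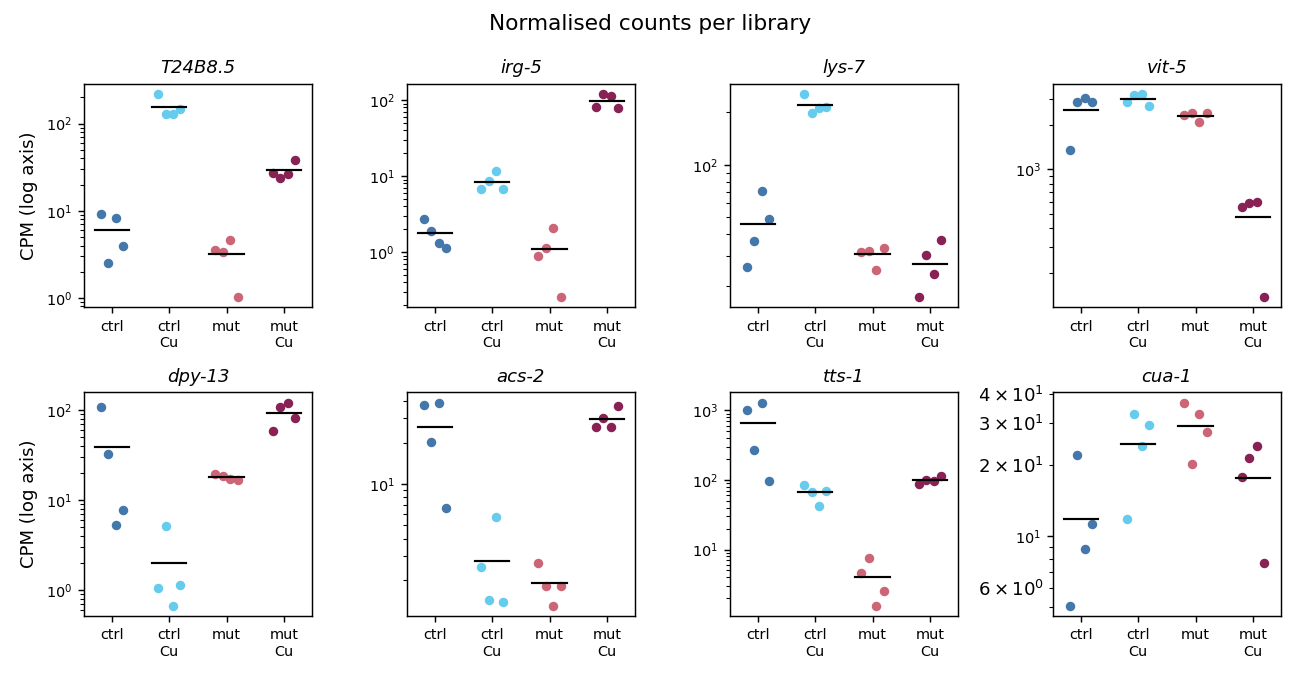
Each point is 1 library, with the 4 groups on the horizontal axis (ctrl, control; mut, mutant; Cu, copper) and CPM on a logarithmic vertical axis; bars are means of 4 libraries. In the copper-treated mutant irg-5 stood at 98 ± 21.7 CPM and vit-5 at 473 ± 224, against 1.09 ± 0.757 and 2290 ± 139 in the untreated mutant.

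Collagen genes had a more positive response in the mutant in 49 of 99 cases and a more negative one in 0 (61 and 1 adjusted over the list alone; median 2.92, adjusted p = 5.02e-25, and adjusted p = 0.554 with an estimated correlation). Among them were col-14 (7.24 ± 1.06), col-65 (7.11 ± 1.06), col-60 (7.04 ± 0.98) and sqt-3 (5.40 ± 0.70). Immune effector genes had 17 of 41 more positive and 1 more negative (27 and 2 adjusted over the list alone; median 1.64, adjusted p = 6.35e-12, and adjusted p = 0.554 with an estimated correlation). Examples were cnc-4 (5.90 ± 0.62, adjusted p = 6.22e-05), irg-5 (4.25 ± 0.60) and the antimicrobial peptide nlp-33 (2.73 ± 0.40). Lectins had 15 of 58 more positive and 3 more negative (22 and 4 adjusted over the list alone; median 1.03, adjusted p = 0.000177, and adjusted p = 0.554 with an estimated correlation). Their clec-3 was at 5.68 ± 0.97, clec-52 at 5.55 ± 0.50 (adjusted p = 1.17e-05), clec-47 at 3.64 ± 0.50 and clec-66 at 3.14 ± 0.50. The list was not called without the long-depleted libraries (adjusted p = 0.0758). Vitellogenins had 4 of 6 more negative and 0 more positive (6 and 0 adjusted over the list alone; median -2.40, adjusted p = 2.07e-08, and adjusted p = 0.554 with an estimated correlation). Here vit-4 was at -3.10 ± 0.52 and vit-5 at -2.51 ± 0.50, while vit-1 (-2.43 ± 0.39) and vit-3 (-2.37 ± 0.48) lost their calls with the length offsets (adjusted p = 0.0914 and 0.0765; list median -1.14, 2 called). In the untreated mutant their median was 0.0038, but -1.06 with the length offsets (6 called lower) and -0.19 without the long-depleted libraries (1 lower).

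Neuropeptide genes had 14 of 39 more positive and 0 more negative (21 and 0 adjusted over the list alone; median 1.61, adjusted p = 2.07e-08, and adjusted p = 0.598 with an estimated correlation). The peptide flp-15 was at 3.04 ± 0.60, and flp-20 (3.29 ± 0.67), flp-8 (3.19 ± 0.63) and flp-10 (1.64 ± 0.35) lost their calls with the covariate (adjusted p = 0.111, 0.0672 and 0.0524). Autophagy and lysosome genes were not called as a list (adjusted p = 0.068, but 0.019 with the length offsets; 10 of 61 more positive and 1 more negative, 12 and 3 adjusted over the list alone). Its asp-14 was at 3.88 ± 0.51, sqst-1 at 2.39 ± 0.36 and asp-5 at 2.09 ± 0.43 beside asp-12. In the lipid breakdown list acs-2 was the 1 call of 31, also 1 adjusted over the list alone (list adjusted p = 0.417). The metallothionein mtl-2 was at 2.35 ± 0.69 (adjusted p = 0.0543) and cuc-1 at 0.81 ± 0.48 (adjusted p = 0.246). T24B8.5, singled out here after its values were seen, rose with copper in the mutant too, by 3.19 ± 0.42 (adjusted p = 0.00032), from 3.16 ± 1.53 to 29.1 ± 6.5 CPM. Its interaction was -1.52 ± 0.57 (adjusted p = 0.119), and -2.49 with the length offsets (adjusted p = 0.00246).

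Further large positive interactions were T26H5.9 (7.94 ± 1.23), B0348.2 (7.60 ± 1.21) and grl-16 (7.41 ± 1.29), each called in all 28 alternatives that tested it. F41F3.3 (7.34 ± 1.34) was lost with the covariate (adjusted p = 0.0844). Large negative ones were AC3.5 (-4.75 ± 0.77, adjusted p = 0.00202) and D1086.3 (-4.64 ± 0.91, adjusted p = 0.00604), each called in 28 of 28 alternatives. With the covariate the calls of che-10 (-5.34 ± 1.23), T04F3.1 (-5.26 ± 1.21), T22B7.7 (-5.25 ± 0.99), K09F6.9 (-4.93 ± 1.05), lam-3 (-4.83 ± 1.19) and T28C6.7 (-4.64 ± 1.04) were lost, with highest adjusted p over the alternatives of 0.184, 0.355, 0.066, 0.0538, 0.396 and 0.126. Genes with a more positive response had a median length of 903 bp and those with a more negative one 2199 bp (1088 and 1210 bp with the length offsets). The count of 527 was 2140 without untreated control replicate 2, and 1943, 350 and 337 without copper-treated control replicates 1, 3 and 4. It was 1031 with DESeq2, 256 with the covariate and 1191 without the long-depleted libraries (511 more positive and 680 more negative, 408 shared).

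**Figure D3:**
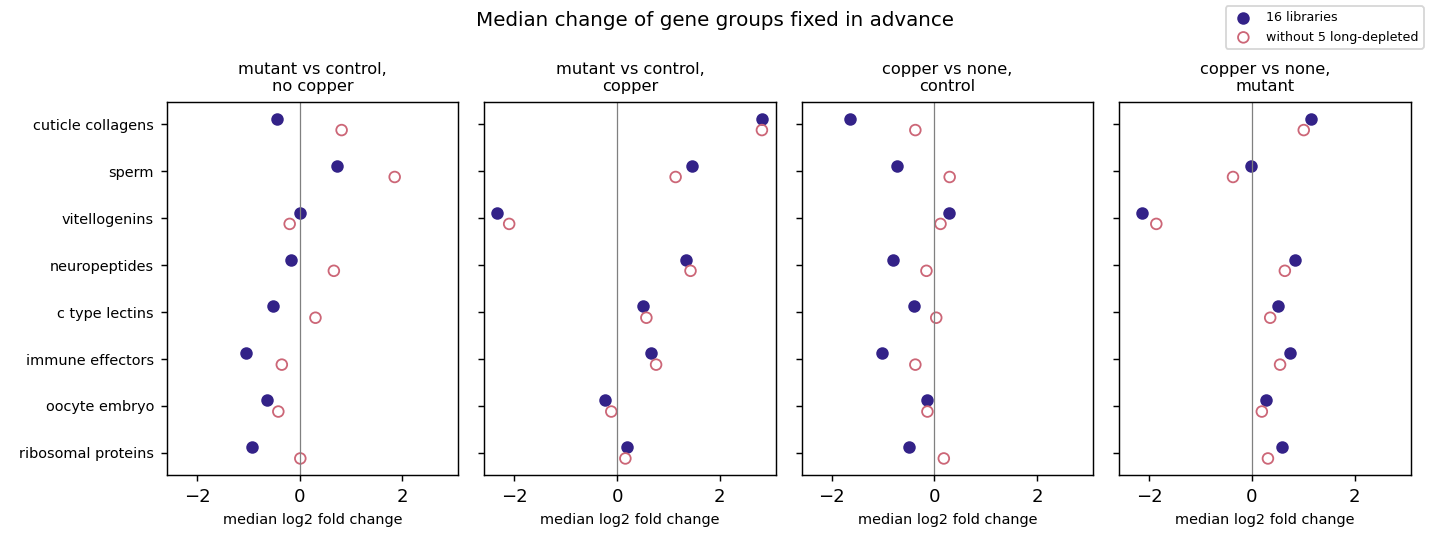
Each row is a gene group fixed in advance, each panel 1 comparison, and the horizontal axis the median log2 fold change of the group's tested genes, with filled points for all 16 libraries and open points without the 5 long-depleted ones. The vitellogenin median lies at -2.33 in the mutant on copper and -2.14 for copper in the mutant, and that of ribosomal protein genes in the untreated mutant moves from -0.93 to 0.013.

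Across all genes tested, the copper response of the mutant ran against that of the control, with a Pearson correlation of -0.48 (jackknife standard error 0.19 over libraries; Spearman -0.57). Genes are not independent replicates. Of the genes called in both, 5 moved the same way and 28 in opposite ways, where independent calls would give 1.39 and 2.5. Without the long-depleted libraries the correlation was -0.17, and 35 moved the same way and 184 in opposite ways (33.9 and 34 for independent calls). The mutant's difference from the control without copper and with copper correlated at -0.0091 (jackknife standard error 0.3). For these comparisons 223 genes were called in both, 169 the same way (157 higher and 12 lower) and 54 in opposite ways, against 65.3 and 83 for independent calls. The numbers were 542 and 183 without the long-depleted libraries, against 215 and 186.

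The untreated mutant and copper-treated control share the untreated control, which by itself makes their changes alike. In a fit to the 12 libraries concerned, changes correlated at 0.76 across 9177 genes (jackknife standard error 0.14), against 0.72 to 0.75 in 20 simulations with only the shared control in common. The covariance was 0.659, against a simulated mean of 0.185. Against separate pairs of the 4 control libraries r ran from 0.47 to 0.52 over the 6 pairs. Of genes called in both, 13 were higher, 43 lower and 0 opposite (edgeR). Independent calls would give 2.9 and 7.07, and simulations gave at most 2. Each pair holds a long-depleted library and no simulation holds unrelated real changes, so likeness beyond shared control and transcript length stays open.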

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

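The tests of ribosomal protein genes without the long-depleted libraries, of the sides of the length limit, of exchanged labels, of both fasting responses, of the fall of the crossed genes in the untreated mutant, of a younger stage and of the sperm genes with copper in the mutant were chosen after the result was seen, and so were the 5 libraries, the 12 crossed genes and the 14 genes examined for outlying libraries. Of 164 groups of 4 libraries tested for a library far from the other 3, 29 had one, where chance gives about 1 in 20.

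Long genes were higher and ribosomal protein genes lower in the untreated mutant. Against the untreated control, 3 of whose libraries are long-depleted, the ribosomal protein median was -0.93, and it was 0.013 without those libraries, which leaves 1 untreated control library, but -0.38 with the length offsets (20 of 80 lower, 0 higher), so how much of that fall few long transcripts carry stays open. Genotype or copper as the whole origin of the axis is argued against, since 3 groups hold libraries on both sides of the limit. The immune effector median of -0.35 without these libraries (-0.347 to 3 digits, -1.05 with them) leaves open how much of the immune fall the axis carries. RNA quality, library preparation and a difference between cultures stay open as origins of the axis and were not tested, since the labels give no batch.

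A set of 12 genes was lower in the untreated mutant and in the copper-treated control, and higher in the copper-treated mutant against either: acs-2, asp-12, clec-52, cnc-4, col-60, icl-1, nlp-33, sodh-1, C18H9.5, F07C6.2, F08B12.4 and Y41C4A.32, the genes outside the naming rule being listed after their values were seen. Their median interaction was 5.1, and 4.67 without the long-depleted libraries. Chosen for this pattern and fitted with 1 untreated control library, these genes leave the share of the length axis open. In that fit their fall in the untreated mutant weakened (median -1.8 to -1.56, with clec-52, nlp-33 and Y41C4A.32 at -0.35, -0.68 and -0.26). A fasting response in the untreated control stays open too: fat-5, fat-6 and fat-7, which fasting would lower, had a median of 0.952 (standard error 0.3) in the untreated against the copper-treated control, but of -0.107 (0.2) without the long-depleted libraries. In the copper-treated mutant their median was -0.441, which leaves such a response open there, and a biological origin in genotype and copper stays open as well. Exchanged labels of the mutant groups cannot be told apart from a true reversal: the 45 genes that rose with copper in the control had a median of 0.0855 with copper in the mutant, with 4 called higher and 1 lower, and the missense allele cannot be read in the counts.

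Collagen and sperm genes were higher and vitellogenins lower in the copper-treated mutant. Without the long-depleted libraries 6 vitellogenins were still called lower and the collagen median was 2.82, which argues against the length axis. A single library is argued against too, since the lowest number of vitellogenins called over the 4 fits without 1 library of that group was 5. A younger stage may fit with late larval collagens and less yolk. The oocyte and embryo median of -0.112 (5 of 31 positive) does not settle it. For yolk, stage and copper cannot be told apart. For collagens the control's fall with copper (-1.65, 1.16 in the mutant) and genotype stay open too. An effect that arose with copper in the mutant is argued against for the sperm genes, whose median there was -0.0202 (90th percentile 0.217), against 0.72 in the untreated mutant and -0.73 with copper in the control; a stage difference on both plates stays open.

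Splits of the same libraries into other groups were run for each count of genes. For the untreated mutant against control (2141 genes, highest other 22), only the real split of 35 reached the count. The same held for the mutant on copper (678, highest other 3) and copper in the mutant (219, highest other 0). This is the smallest share of 35, and mixed splits hold real differences within groups, so chance is not excluded. Nor is it for the interaction (527, 4 of 100, highest other 2781) or copper in the control (174, 2 of 35, highest other 4028). The split with 4028 genes sets the 4 long-depleted libraries against the other 4. It and the 2781, several times the real counts, point to a structure of the samples. With the length covariate the 174 became 1.0e+02. For the number of lists called, chance could not be excluded in any comparison: 10 lists in the untreated mutant (17 of 35 splits as many; highest other 12), 11 in the mutant on copper (7 of 35; 12), 9 for copper in the control (10 of 35; 11), 9 for copper in the mutant (11 of 35; 12) and 10 for the interaction (19 of 100; 14). Nor could it for the correlation of -0.48 between the copper responses (7 of 100 splits; lowest other -0.58).

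The interaction, a tested difference between the copper responses of control and mutant, was called for 527 genes. The largest positive values were 8.42 for E01G4.6, 8.06 for K02E11.10, 7.94 for T26H5.9, 7.93 for tts-1, 7.69 for col-63, 7.6 for B0348.2, 7.41 for grl-16, 7.34 for F41F3.3, 7.24 for col-14 and 7.16 for acs-2. The largest negative values were -5.34 for che-10, -5.26 for T04F3.1, -5.25 for T22B7.7, -5.13 for C42D4.2, -4.96 for C41A3.2, -4.93 for K09F6.9, -4.83 for lam-3, -4.75 for AC3.5, -4.64 for T28C6.7 and -4.64 for D1086.3. E01G4.6, K02E11.10, col-63, C42D4.2 and C41A3.2 had 3 counts or fewer in a group, so their fitted values depend on the prior count. With the covariate C42D4.2 and C41A3.2 were no longer called (adjusted p = 0.0651 and 0.112, the highest over their alternatives).

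Scores of lists are as defined above. Untreated control replicate 2 lay apart from its group in the sperm score, at -1.2 against 0.0349 to 0.15. Replicate 1 of the same group lay apart in the scores of detoxification enzymes (0.109 against -0.426 to -0.365), collagens (1.5 against -0.661 to -0.411) and vitellogenins (-0.332 against 0.653 to 0.726), in clec-45 (2.75 against 0 CPM) and in vit-5 (1340 against 2830 to 3030 CPM).

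Copper-treated control replicate 1 lay apart in the balance of long and short genes (-0.869 against 0.947 to 1.09), the vitellogenin share of counts (1.63% against 2.49% to 2.56%) and mtl-2 (57.7 against 20.8 to 23.3 CPM). Its scores lay apart for metal-responsive genes (0.2 against -0.3 to -0.264), immune effectors (0.231 against -0.38 to -0.287), oocyte and embryo genes (0.547 against -0.0333 to 0.0134), autophagy and lysosome genes (0.0325 against -0.124 to -0.104), nuclear genes of oxidative phosphorylation (0.47 against -0.367 to -0.303) and neuropeptides (-0.0746 against -0.78 to -0.706).

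Untreated mutant replicate 3 lay apart in the ABC transporter score (0.487 against 0.413 to 0.424), the vitellogenin score (0.317 against 0.509 to 0.544) and lys-7 (25 against 31.7 to 33.2 CPM), and replicate 4 in fat-7 (124 against 93.9 to 96 CPM). Copper-treated mutant replicate 4 lay apart in the balance of long and short genes (-2.28 against 0.191 to 0.467), the TMM factor (0.753 against 1.06 to 1.11), the ribosomal protein share (38.7% against 30.4% to 31.8%), the vitellogenin share (0.135% against 0.78% to 0.853%) and vit-5 (138 against 561 to 602 CPM). Its scores lay apart for copper handling genes (0.373 against -0.251 to -0.157), histones (0.563 against -0.264 to -0.194), ribosomal proteins (0.734 against -0.167 to -0.0567), oxidative phosphorylation (0.493 against -0.297 to -0.171) and vitellogenins (-3.1 against -1.24 to -1.12).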

How the results depend on the processing

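The length offsets, the covariate and the fit without the 5 long-depleted libraries were chosen after the data were seen. Of 333 pairs of a gene and a comparison followed, 267 were called, of which 186 kept direction and call in every alternative set beforehand that gave a value and 81 lost the call in at least 1. Calls lost were 6 with DESeq2 size factors, 2 with upper-quartile factors, 20 with no filter, 0 with the stricter filter (edgeR), 0 with DESeq2 (19 gained), 32 with limma-voom, 20 in fits to the libraries of the comparison alone, 29 with the replicate block, 14 with the length offsets, 55 with the covariate and 34 without the long-depleted libraries (26 gained). Reversed without those libraries, in the untreated mutant, were ttm-1 (0.461 against -1.14) and rpl-35 (0.00252 against -1.07); the cause was not tested. The 2141 genes of the untreated mutant against control became 1419 with the block and 880 with the covariate, the 678 of the mutant on copper 1530 with the covariate and 2288 without the long-depleted libraries. The 174 genes of copper in the control became 440 with DESeq2, 45 with limma-voom, 13 in the fit to its own libraries, 64 with the block, 1.0e+02 with the covariate (46 higher and 58 lower) and 468 without the long-depleted libraries. The 219 of copper in the mutant became 432 with DESeq2, 472 in the fit to its own libraries, 403 with the covariate and 1420 without the long-depleted libraries, and the 527 of the interaction 1031 with DESeq2, 256 with the covariate and 1191 without the long-depleted libraries. With 1 library left out the counts ran, in the same order, from 735 to 3838, 434 to 840, 44 to 849, 115 to 334 and 337 to 2140. The cause of these shifts was not tested. With an estimated correlation (camera) 0 lists were called in each of the 5 comparisons, with 0, 7, 0, 3 and 1 lists at an unadjusted p under 0.05. The 10 lists of the untreated mutant became 16 with the covariate, and the 9 of copper in the control 3 with the covariate and 0 with fry (5 at an unadjusted p under 0.05). With fry the 9 of copper in the mutant became 4 and the 10 of the interaction 5. Lists called with 1 library left out ran from 9 to 11, 9 to 16, 9 to 11, 8 to 9 and 9 to 11. The correlation of the copper responses, -0.48, was -0.19 with the covariate and -0.17 without the long-depleted libraries, and ran from -0.52 to -0.33 with 1 library left out. That of the untreated mutant with the copper-treated control, 0.76, was 0.55 with the covariate and 0.69 to 0.84 with 1 library left out, and that of the mutant's differences without and with copper ran from -0.17 to 0.16. Of 24 pairs of equally numbered libraries from different groups 6 had r above 0.1 across genes, and in 4 the equal number gave the best r, so the numbers were not read as pairs. Depth limits folds of genes with 3 counts or fewer in a group to bounds or wide intervals.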

Other observations

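The choice of which uncalled lists to describe here was made after the results were seen. The fits without the long-depleted libraries were chosen then too, while the tests of the lists themselves were set before. In the untreated mutant against the untreated control, proteasome genes fell in 12 of 33 cases with 0 higher (14 and 0 adjusted over the list alone; median -0.46, adjusted p = 0.000285, and adjusted p = 0.548 with an estimated correlation). Among them were the proteasome subunits pas-3 (-1.03 ± 0.29), pbs-7 (-0.93 ± 0.28), pbs-2 (-0.97 ± 0.30) and pbs-5 (-1.11 ± 0.34). The count was 2 lower without the long-depleted libraries, with these 4 not among them. Nuclear genes of oxidative phosphorylation fell in 8 of 43 cases with 0 higher (15 and 0 adjusted over the list alone; median -0.67, adjusted p = 4.41e-06, and adjusted p = 0.686 with an estimated correlation). The complex I gene nuo-2 was at -0.96 ± 0.29, the ATP synthase gene asg-1 at -1.07 ± 0.34 and cox-7C at -1.1 ± 0.36. In the fit without the long-depleted libraries 0 of these genes were called (edgeR; median -0.012). ABC transporter genes rose in 5 of 22 cases with 0 lower (7 and 0 adjusted over the list alone; median 1.16, adjusted p = 0.00199, and adjusted p = 0.548 with an estimated correlation). Its haf-9 was at 1.75 ± 0.37. The list was not called with the length offsets (adjusted p = 0.594) or without the long-depleted libraries (adjusted p = 0.21). Fatty acid synthesis genes rose in 4 of 18 cases with 0 lower (5 and 0 adjusted over the list alone), with the fatty acid synthase fasn-1 at 1.5 ± 0.51. The latter was at 0.24 without the long-depleted libraries (adjusted p = 0.517) and lost its call in 17 of 29 alternatives (adjusted p from 0.00484 to 0.586). That list was not called (adjusted p = 0.418; median -0.07, mean 0.26), and 8 rose without the long-depleted libraries (adjusted p = 1.19e-05). Muscle genes rose in 8 of 26 cases and fell in 4 (11 and 7 adjusted over the list alone; list adjusted p = 0.252, but 0.000123 without the long-depleted libraries), with the giant sarcomere protein unc-89 at 3.36 ± 0.71. Lipid breakdown genes rose in 2 of 31 cases and fell in 7 (the same adjusted over the list alone; list adjusted p = 0.418), and intestine genes rose in 3 of 20 and fell in 6 (3 and 7 adjusted over the list alone; list adjusted p = 0.247). C-type lectins rose in 8 of 58 cases and fell in 12 (8 and 14; median -0.52, list adjusted p = 0.238), but 7 rose and 4 fell without the long-depleted libraries (median 0.31). Collagens rose in 4 of 99 and fell in 5 (3 and 5; list adjusted p = 0.418), where 37 collagens rose and 9 fell without the long-depleted libraries. Germline genes fell in 4 of 26 cases with 0 higher (4 and 0; list adjusted p = 0.487), and 7 fell without the long-depleted libraries.

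Some lists were called in further comparisons, though few of their members were called singly by edgeR. In the mutant on copper these were germline genes (0 of 26; median -0.29, adjusted p = 0.00276, and adjusted p = 0.187 with an estimated correlation). Others were oocyte and embryo genes (0 of 31; median -0.23, adjusted p = 0.012, and adjusted p = 0.774 with an estimated correlation) and proteasome genes (0 of 33; median -0.14, adjusted p = 0.0326, and adjusted p = 0.774 with an estimated correlation). Germline and oocyte genes were not called with the length offsets (medians -0.13, adjusted p = 0.0981 for each), nor oocyte and proteasome genes without the long-depleted libraries (0.0575 and 0.0626). For copper in the control they were ribosomal protein genes (0 of 80; median -0.50, adjusted p = 9.21e-08, and adjusted p = 0.623 with an estimated correlation) and sperm genes (0 of 50; -0.73, adjusted p = 3.58e-07). Others were oxidative phosphorylation (0 of 43; -0.58, adjusted p = 1.22e-06), histones (0 of 35; -0.49, adjusted p = 0.000129), neuropeptides (0 of 39, and 1 higher and 11 lower adjusted over the list alone; -0.81, adjusted p = 0.000236) and ABC transporters (1 of 22 higher; 0.43, adjusted p = 0.00185). Sperm genes and these last 4 had adjusted p = 0.621 with an estimated correlation. With the length offsets ribosomal protein, sperm, histone, neuropeptide and ABC transporter genes were not called (medians -0.0092, -0.064, -0.075, -0.31 and 0.017; adjusted p = 0.96, 0.782, 0.413, 0.193 and 0.888). Oxidative phosphorylation (0.0543), neuropeptides (0.73) and ABC transporters (0.27) were not called without the long-depleted libraries. The medians of ribosomal protein and sperm genes turned positive without the long-depleted libraries, at 0.18 and 0.30, where the 1 untreated control library has a low sperm score. For copper in the mutant they were ribosomal protein genes (0 of 80; median 0.59, adjusted p = 8.26e-12), histones (1 of 35 higher; 0.43, adjusted p = 0.00542) and oocyte and embryo genes (0 of 31; 0.27, adjusted p = 0.0313), each with adjusted p = 0.95 with an estimated correlation. With the length offsets the ribosomal protein median was 0.22 and the histone call ended (median 0.092, adjusted p = 0.662) and without the long-depleted libraries (0.165). In all, 54 ribosomal protein genes rose without the long-depleted libraries (median 0.31). For the interaction they were ribosomal protein genes (1 of 80 positive, and 52 adjusted over the list alone; median 1.09, adjusted p = 3.64e-13, and adjusted p = 0.666 with an estimated correlation) and histones (3 of 35 positive; 0.99, adjusted p = 6.08e-05, and adjusted p = 0.666 with an estimated correlation). Others were oxidative phosphorylation (0 of 43; 0.81, adjusted p = 0.000217, and adjusted p = 0.768 with an estimated correlation), ABC transporters (0 of 22; -0.75, adjusted p = 0.0186, and adjusted p = 0.666 with an estimated correlation) and sperm genes (0 of 50; 0.74, adjusted p = 0.0175, and adjusted p = 0.768 with an estimated correlation). With the length offsets the ribosomal protein median was 0.24, and histones (median 0.23, adjusted p = 0.348), oxidative phosphorylation (0.27, 0.0759) and ABC transporters (-0.13, 0.71) were not called, and the last 2 were not called without the long-depleted libraries (0.413 and 0.335). The sperm median of the interaction turned to -0.40 with the length offsets and to -0.69 without the long-depleted libraries.

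The remaining lists were called in none of the 5 comparisons by camera at the preset correlation with all libraries. Their smallest adjusted p was 0.0593 for neuronal genes, 0.0689 for the unfolded protein response of the endoplasmic reticulum, 0.0813 for intestine, and 0.0979 for copper handling, MAPK stress signalling and lipid breakdown. It was 0.203 for hypoxia and hydrogen sulfide, 0.215 for molting, 0.322 for metal response, 0.326 for heat shock, 0.403 for methionine and transsulfuration, 0.405 for oxidative stress, 0.447 for the intracellular pathogen response and 0.613 for the mitochondrial unfolded protein response. Other tests called some of them. In the untreated mutant fry, testing direction, called hypoxia and hydrogen sulfide (0.00533), molting (0.0243) and neuronal genes (0.0129), and in the mutant on copper the endoplasmic reticulum list (0.0278), molting (0.0278) and neuronal genes (0.004). Camera with the length offsets called molting (0.0263) and neuronal genes (0.00441) in the mutant on copper, lipid breakdown (0.01) and intestine (0.00683) with copper in the control, and MAPK stress signalling (0.0413) with copper in the mutant. It called methionine and transsulfuration without the long-depleted libraries in the untreated mutant (0.00284) and with copper in the control (0.0268), where lipid breakdown (0.0268) and intestine (0.0463) were called too. The list of mitochondrially encoded genes was not tested, since its 12 genes held 0 counts, and iron handling had fewer than 3 tested members. Median, mean and test of a list differed in sign, among lists discussed and not called, for metal-responsive genes, vitellogenins, fatty acid synthesis and germline genes in the untreated mutant. It did so for copper handling, lipid breakdown, autophagy and lysosome, and intestine genes in the mutant on copper, for detoxification enzymes with copper in the control, and for copper handling and lipid breakdown genes with copper in the mutant. No list that was called showed such a difference.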
